A study of Mus musculus with 6 samples.

How the data were processed

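RNA of mouse CD4+ T cells was prepared with a PAXgene kit and sequenced from Illumina TruSeq libraries as single reads of 50 bases, per the labels' protocols. The authors deposited 1 table of whole-number read counts, with 13177 RefSeq transcript accessions as rows and the 6 libraries as columns. Bowtie, R 3.4.2 and the genome build GRCm38 are named in the submitters' processing notes, with no role given. The program that counted reads, its treatment of reads that match several places, the annotation and any filter on rows are not given in the sources used here, nor is whether the counting used strand. Counts of genes with near-identical copies, overlapping neighbours or antisense partners are therefore uncertain. Every row had at least 1 count, and the values were used as deposited. Actb had 1 to 5 counts and Gapdh 1 to 11 counts in every library, so whether the rows hold ordinary counts per gene is uncertain, and every CPM and fold change carries that limit. Columns were matched to samples by their titles, and 0 columns lay outside the series.

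Accessions were given symbols and GRCm38 coordinates through a RefSeq gene table of GRCm38.p6 (12824 accessions) or GENCODE release M21 (50 further accessions), and 303 stayed unnamed. The longest annotated 3' UTR of each gene, from GENCODE M21, was searched for seed matches, which was possible for 12715 accessions.

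Library depth ranged from 4564010 to 13675127 counts. Between 57.7% and 68.7% of a library's counts fell on its 100 most abundant accessions. The median count per accession lay between 10 and 30, so low counts may limit precision for much of the table, which was not tested. Intervals from counting would cover counting error only, since the reads carried no molecular identifiers.

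Groups were compared with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter given the groups (8308 accessions kept) and the quasi-likelihood F test with robust settings in its default form, two-sided, with Benjamini-Hochberg adjustment at 0.05. Standard errors were computed as the absolute log2 fold change over the square root of F. CPM were computed from the deposited counts and TMM-scaled library sizes. The fit had the group as its only term. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested members. The 36 lists held 661 genes, of which 594 were matched, and covered miR-155 targets, T cell states and lineages, signalling, stress, metabolism and markers of other cell types. For the seed comparison, log2 fold changes were regressed on the presence of a site, log 3' UTR length and GC content, and the difference for the 7-mer AGCATTA was ranked among all 7-mers of its base composition. Shares of counts were compared with two-sided exact permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. Over the 36 shares the lowest Benjamini-Hochberg adjusted p was 0.9.

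Except for the form of the quasi-likelihood fit, groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took (a) the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap and whose higher group averaged at least 5 CPM, leaving out clone and predicted names and pseudogenes, (b) up to 4 members per list among called genes and (c) the 22 genes listed in advance. As no gene was called, (a) and (b) named none, and any other gene was chosen after its values were seen. Alternatives were a replicate block, RLE and upper-quartile scaling, DESeq2 1.42.0, no filter, a mean of at least 5 CPM, a fold-change threshold, an estimated correlation, fry, other definitions of a seed site and leaving out each replicate. An alternative pseudocount applied to normalized values only and was not needed for counts. The form of edgeR's quasi-likelihood fit was not named in advance, and the default of the installed version was taken after results of both forms had been seen. The newer form and limma-voom were added as alternatives after seeing the data.

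The scripts were tested on simulated counts of the 8308 genes with the real means, library sizes and dispersions and 200 changed genes. At the dispersions estimated from these libraries edgeR made no false calls. It recovered 0 of 67 genes changed by 4 and 0 of 66 changed by 6 on the log2 scale. DESeq2 recovered 29 of 67 and 52 of 66, with 108 false calls. With no gene changed, edgeR called 0 genes and DESeq2 called 84. At a dispersion 20 times smaller edgeR recovered 67 of 67 genes changed by 2 on the log2 scale, with 12 false calls. At the dispersions estimated from these libraries, a simulated shift of the cell cycle genes by 1 on the log2 scale gave a camera p of 0.891. A shift by 2 gave 9.74e-07. Genes were drawn independently and each setting was drawn once, so the simulations may show more power than the real libraries allow.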

Results

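The transcriptome of mouse CD4+ T cells, the helper T lymphocytes, was measured by sequencing of RNA after transfer of a synthetic oligonucleotide of miR-155, a microRNA induced in activated lymphocytes. The 6 libraries fell into 2 groups of 3, labelled as control at 0 h and as collected 8 h after transfection. Summed counts per library were 6455076, 4564010 and 12303358 in controls 1 to 3 and 8536899, 13675127 and 6243803 in 8 h replicates 1 to 3. Control and 8 h samples differed in time as well as in exposure, because no sample was collected at 8 h without the oligonucleotide, and the treatment label of the controls also names the oligonucleotide. Nothing in the labels states that replicates came from separate animals or cultures. P-values of single genes therefore measure only the spread between these samples, which may be technical. Those of camera with its preset correlation also rest on the spread between genes. Each of the 8 h samples is described as CD5+ in its description and as CD4+ T cells in its source label.

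Over the 8308 tested genes, Pearson's r of log2 CPM across genes averaged 0.457 for pairs within a group and 0.446 for pairs between groups. Over the 1224 genes with a mean of at least 100 CPM the averages were 0.153 and 0.106. Genes are not independent replicates, and these correlations carry no test. Lck, the proximal T cell receptor kinase, had 171, 226 and 162085 counts in controls 1 to 3 and 14436, 29948 and 367 counts in the 8 h replicates. Cd3d, a subunit of the receptor complex, had 1338, 73937 and 13051 counts in the controls and 953, 3584 and 2895 counts at 8 h. Both genes were chosen after their values were seen. Among the 1065 tested genes with a mean of at least 1000 counts, the median ratio of the highest to the lowest library within a group was 25.1.

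**Figure D1:**
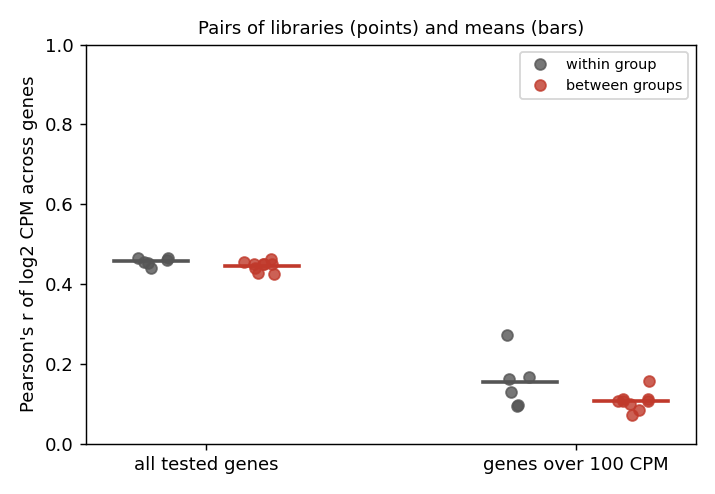
Pearson's r of log2 CPM across genes for each pair of libraries (points) within a group and between groups, with means as bars, over all tested genes and over genes with a mean of at least 100 CPM. The means lie at 0.457 within and 0.446 between groups over all tested genes, and at 0.153 and 0.106 over the abundant genes.

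The first comparison asked which genes differed between cells 8 h after transfer of miR-155 and control cells. Ifng and Il2 had higher values in every 8 h library than in every control, but neither passed the test. Ifng, which encodes interferon gamma (chromosome 10, 118441046 to 118445894, GRCm38), stood at 1.98 ± 1.33 CPM (SD, n = 3) in controls and 42.7 ± 9.05 CPM (SD, n = 3) at 8 h, from 5, 8 and 38 counts against 405, 428 and 333 counts. Its log2 fold change was 4.41 ± 1.95 (SE), with an adjusted p of 0.538 in edgeR's quasi-likelihood test. Il2, the T cell growth factor, stood at 13.2 ± 10.1 CPM (SD, n = 3) in controls and 61.2 ± 14.7 CPM (SD, n = 3) at 8 h, with a log2 fold change of 2.22 ± 1.79 (SE) and an edgeR adjusted p of 0.745. Without control replicate 3 the log2 fold change was 5.11 for Ifng and 2.97 for Il2. Without control replicate 1 it was 4.046 for Ifng and 1.745 for Il2. Across the 8308 genes tested, edgeR's quasi-likelihood test called 0 genes at an adjusted p under 0.05, the lowest adjusted p being 0.316. At an unadjusted p under 0.05 it gave 709 genes, 375 with higher and 334 with lower values at 8 h. DESeq2's Wald test, run as an alternative, called 399 genes, 194 higher and 205 lower, with 1371 at an unadjusted p under 0.05. It gave no adjusted p for 1720 of the genes, among them 916 set aside as outliers without a p, such as Lck. Its calls thus come from fewer genes than those of edgeR. Added alternatives called 0 genes, with 984 at an unadjusted p under 0.05 in the newer quasi-likelihood fit and 400 in limma-voom. All 3 libraries of one group lay above all 3 of the other for 475 genes higher and 422 genes lower at 8 h, together 10.8% of tested genes, against 10% given by chance.

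Of 22 genes fixed in advance for their link to miR-155 or to helper T cell lineages, 20 were matched in the table, 11 had enough counts to be tested, and 0 passed edgeR's threshold, either over all genes or adjusted over the list alone. DESeq2 called 1 of them, Ifng (adjusted p = 0.00437, against up to 0.998 over the alternatives). Socs1, a suppressor of cytokine signalling and a reported miR-155 target with 1 seed match in its 3' UTR, had 96.6 ± 115 CPM (SD, n = 3) in controls and 244 ± 212 CPM (SD, n = 3) at 8 h. Peli1 had 6.50 ± 5.33 CPM in controls and 1.19 ± 0.595 CPM at 8 h (SD, n = 3 each), with a log2 fold change of -2.44 ± 1.55 (SE). Ifngr1, a chain of the interferon gamma receptor, had a log2 fold change of -2.18 ± 1.91 (SE), and Maf one of -1.43 ± 1.32 (SE). For these 4 genes the edgeR adjusted p lay between 0.659 and 0.877. The log2 fold change of Socs1 ran from 0.32 without 8 h replicate 2 to 3.01 without control replicate 3, and that of Maf from -2.68 to -0.31 without the same libraries. That of Peli1 was -1.66 without control replicate 3, and that of Ifngr1 was -3.66 without 8 h replicate 3. Inpp5d, Jarid2, Bach1, Cebpb, Ets1 and Ptpn2 each had at most 14 counts in any library and were not tested. Mir155hg and Mir155 were not matched, and the transfer of the oligonucleotide was not checked here.

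Among lineage genes, Tbx21, the Th1 transcription factor, had 65.9 ± 28.2 CPM in controls and 19.8 ± 15.2 CPM at 8 h (SD, n = 3 each). Its value in every 8 h library lay below that in every control, opposite to Ifng and Il2. Its log2 fold change was -1.74 ± 1.77 (SE), with an edgeR adjusted p of 0.807, and was -2.57 without 8 h replicate 2. Gata3, the Th2 factor, ranged from 6.96 to 242 CPM in the controls and from 6.81 to 465 CPM at 8 h. Foxp3, the factor of regulatory T cells, had a log2 fold change of 1.75 ± 1.46 (SE), which was 0.50 without 8 h replicate 1 and 3.24 without control replicate 3. Il17a had 1, 1 and 0 counts in the controls and 24, 0 and 0 at 8 h, below the filter for testing. Cd4 had 5 to 10 counts in every library and was not tested, whereas Cd5 had 3020 to 27651 counts, with 1569 ± 1205 CPM in controls and 1740 ± 1964 CPM at 8 h (SD, n = 3 each). Cd8a had 3.45 ± 1.95 CPM in controls and 5.27 ± 4.89 CPM at 8 h (SD, n = 3 each). The sign of the log2 fold change turned without control replicate 3 for Cd5 (-0.33) and Ifngr1 (1.0), without 8 h replicate 3 for Cd5 (-1.33) and Cd8a (-0.29), and without 8 h replicate 2 for Gata3 (-1.14), which stood at 0.90 with all libraries, 2.76 without control replicate 1 and 1.52 without 8 h replicate 3. It also turned with replicate number as a block for Cd5 (-0.44) and Gata3 (-0.56).

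**Figure D2:**
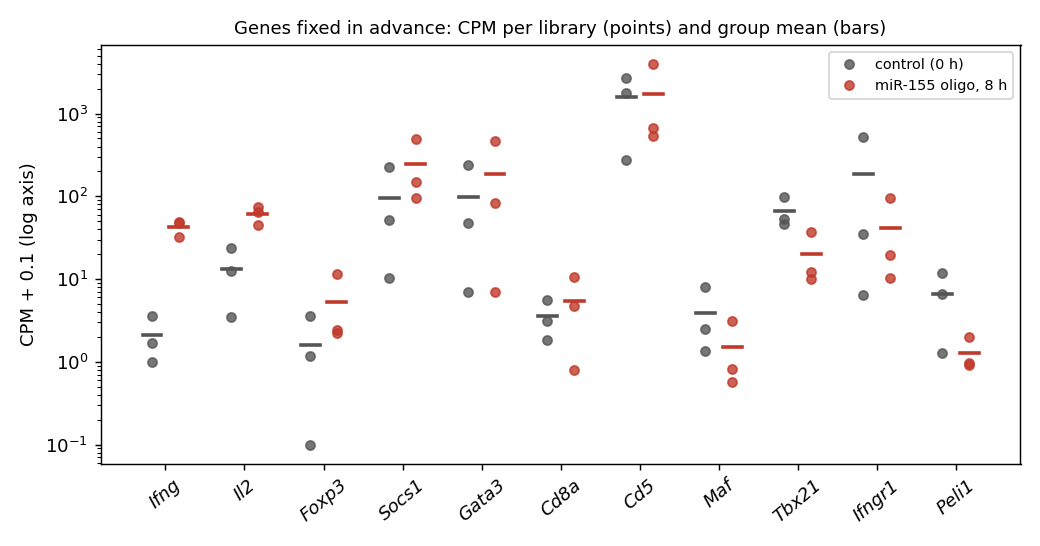
CPM plus 0.1 on a log axis for the 11 tested genes fixed in advance, with 1 point per library and bars for the group means, in controls (grey) and at 8 h (red). The 3 points of Ifng at 8 h lie between 32.2 and 48.3 CPM and those of the controls between 0.894 and 3.47 CPM, while the groups overlap for most other genes.

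The second comparison asked whether genes of one pathway or cell type moved together. Of 31 lists with at least 5 tested members, 1 passed camera, which compares a list with the other genes, namely the cell cycle list. Its mean log2 CPM difference exceeded that of the other genes by 1.64 (camera adjusted p = 0.00837). With an estimated correlation of 0.0185 the list did not pass camera (unadjusted p = 0.0266, adjusted p = 0.624). With the preset 0.01 camera takes its degrees of freedom from the number of genes, and with an estimate from the libraries. The preset p therefore takes less account of how few libraries there were. By fry the list did not pass (adjusted p = 0.181). Of its 19 tested members 13 had higher and 6 lower values at 8 h, and 0 passed edgeR's threshold singly, over all genes or adjusted over the list alone, whereas DESeq2 called 3, Plk1, Rrm1 and Mcm5. Plk1, a mitotic kinase, had 10, 55 and 127 counts in the controls and 2778, 18453 and 8950 at 8 h, with a log2 fold change of 6.95 ± 2.69 (SE). Rrm1, a ribonucleotide reductase subunit, had 2, 2 and 6 counts against 54, 104 and 23. Mcm5, a subunit of the replicative helicase, had 280, 281 and 249 counts against 14918, 9994 and 427. In the other direction, Ccnd3, a G1 cyclin, had a log2 fold change of -2.10 ± 2.13 (SE) and Cdk6, its partner kinase, one of -1.92 ± 1.70 (SE). The members named here were chosen after their values were seen. The list took 0.238 ± 0.147% of counts in controls and 0.688 ± 0.199% at 8 h (SD, n = 3 each), the groups not overlapping. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. Shares of 4 of the 36 lists reached that p, where chance gives 10%. In the same libraries, markers of cytotoxic and natural killer cells took 0.271 ± 0.139% of counts in controls and 0.0339 ± 0.00722% at 8 h (SD, n = 3 each; exact permutation p = 0.1). The list no longer passed without control replicate 1 (camera adjusted p = 0.0861), without control replicate 3 (0.0716) or without 8 h replicate 2 (0.203).

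**Figure D3:**
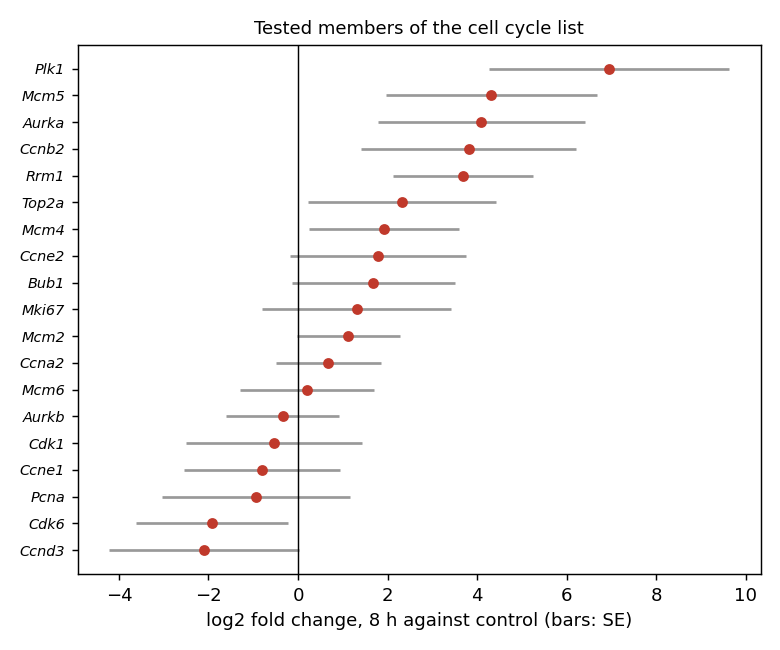
Log2 fold change at 8 h against control, with its SE as bars, for the 19 tested members of the cell cycle list. Estimates of 13 members lie above 0 and those of 6 below, from 6.95 for Plk1 to -2.10 for Ccnd3.

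Markers of cytotoxic and natural killer cells, which could enter a CD4+ preparation, had lower values at 8 h in 7 of 10 tested members without passing the test (camera adjusted p = 0.0579). With an estimated correlation the adjusted p was 0.624. Gzma, a granule protease, had 430, 1090 and 10104 counts in the controls and 398, 307 and 65 at 8 h, and Prf1, the pore-forming protein perforin, had 220, 5 and 1010 against 7, 56 and 9. Genes of T cell trafficking and adhesion had lower values in 6 of 8 tested members (camera adjusted p = 0.0752), with Cxcr4, a chemokine receptor, at 334, 470 and 498 counts in controls and 19, 27 and 124 at 8 h. By fry, which tests whether a list's genes move one way on balance, this list was the only one past the threshold (adjusted p = 0.00314). Its estimated correlation lay below 0, at -0.108, and its camera adjusted p with that estimate was 0.624. Trafficking genes took 0.386 ± 0.224% of counts in controls and 0.0439 ± 0.0106% at 8 h (SD, n = 3 each; exact permutation p = 0.1). Of 18 tested genes of ribosome biogenesis, 14 had higher values at 8 h (camera adjusted p = 0.0579), among them Rrp9 with 17, 44 and 104 counts in controls and 197, 3551 and 1237 at 8 h. Erythroid and platelet markers had lower values in 5 of 6 members (camera adjusted p = 0.0752) and Th17 genes in 4 of 5 (camera adjusted p = 0.229). Without control replicate 2, the camera test passed the threshold for ribosome biogenesis and for the cytotoxic markers (adjusted p = 0.0216 for both), and without 8 h replicate 3 for ribosome biogenesis (0.00894). With all libraries and an estimated correlation the adjusted p of ribosome biogenesis was 0.743. None of the members named here passed edgeR's test, and DESeq2 called Gzma, Prf1 and Rrp9. All members named here were chosen after their values were seen.

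The reported miR-155 targets, a list drawn up from the literature, had lower values at 8 h in 15 of 23 tested members and higher values in 8 (camera adjusted p = 0.841). T cell identity genes split into 6 higher and 5 lower, Th1 genes into 4 higher and 8 lower, Th2 genes into 6 and 3, and regulatory T cell genes into 3 and 7. Early activation genes split into 10 higher and 5 lower, while their share of counts was 1.20 ± 0.729% in controls and 0.218 ± 0.130% at 8 h (SD, n = 3 each; exact permutation p = 0.1). Nr4a1, an immediate early nuclear receptor, had 89, 282 and 71 counts in controls and 510, 5343 and 1331 at 8 h, while Batf, an AP-1 family factor, had 1752, 7423 and 19326 counts in controls and 104, 203 and 512 at 8 h. Both were chosen after their values were seen, and DESeq2 called Batf but not Nr4a1. Adjusted p values of the 25 lists with an unadjusted camera p of at least 0.05 lay between 0.312 and 0.972. The median, the mean and the test differed in sign for 8 lists, namely T cell identity, early activation, Th2, NF-kB, unfolded protein response, glycolysis, cytosolic ribosomal proteins and monocyte markers. Over all lists 3 members passed when adjusted over the list alone. These were Il1r1, a receptor for interleukin 1 placed in the Th17 list, with 10, 84 and 772 counts in controls and 3, 0 and 0 at 8 h, Dgcr8, a microRNA processing factor, with 0, 1 and 6 against 27, 44 and 65, and Alas2, an enzyme of haem synthesis, with 13, 42 and 17 against 0, 1 and 0. Lists of co-inhibitory receptors, PI3K signalling, CD8 T cell and neutrophil markers had too few tested members for a test, and none of the mitochondrially encoded genes was matched.

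The third comparison asked whether transcripts with miR-155 seed matches had lower values after transfer of the oligonucleotide. The 918 tested genes with at least 1 match to the seed of miR-155-5p in the longest annotated 3' UTR had a mean log2 fold change of -0.09, and the 7114 genes without a match one of 0.07. Adjusted for length and GC content of the 3' UTR the difference was -0.17 ± 0.08 (SE across genes, which are not independent), and -0.08 without 8 h replicate 3. It did not pass the camera test (p = 0.478 with the preset correlation and p = 0.231 with an estimated correlation). Genes with the longest match, the 8mer, numbered 214 and differed by -0.09 ± 0.15 (SE). For AGCATTA alone, the difference ranked 25 from the lowest among itself and 419 other 7-mers of the same base composition. A share of 0.0573 of the others gave a difference as low, and most of these held the bases CG side by side. Genes with a match to the seed of the passenger strand, miR-155-3p (GGTAGGA), numbered 517 and differed by -0.10 ± 0.10 (SE). Counts were also simulated at the dispersions estimated from these libraries. There a shift of -0.50 in the genes with a site was estimated at -0.39 ± 0.06 (SE) with a camera p of 0.0414. A shift of -0.25 was estimated at -0.31 ± 0.06 (SE) with a camera p of 0.165. The simulated SE was smaller than the 0.08 of the real data, so the simulation may overstate what could be detected.

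**Figure D4:**
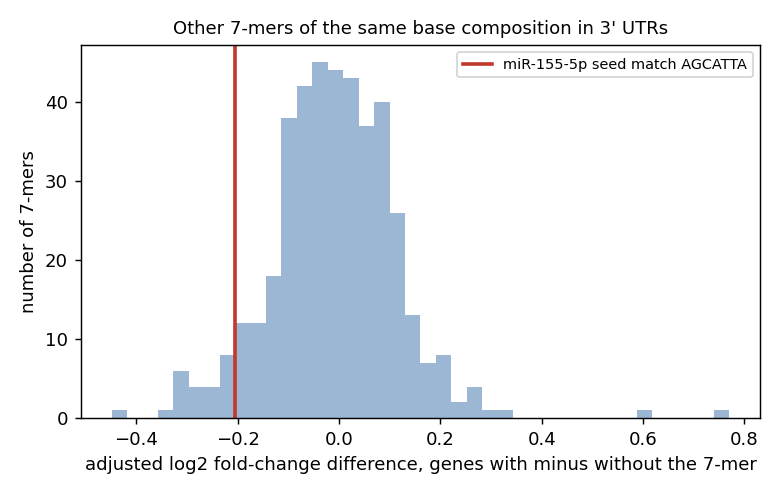
Distribution of the adjusted log2 fold-change difference between genes with and without each of 419 other 7-mers of the same base composition, with the value of AGCATTA as a red line. The line lies at -0.21, rank 25 from the lowest.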

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

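The newer quasi-likelihood fit and limma-voom were chosen after seeing the data. The count of genes differing between 8 h and control was 0 under the replicate block, RLE and upper-quartile scaling and both filters. It was also 0 with the fold-change threshold, both added tools and without each replicate (0 to 0). Residual correlations of same-numbered libraries were -0.0107, 0.0151 and -0.0039. With so wide a spread between libraries, these do not decide whether replicate numbers paired the samples. In simulated counts at the dispersions estimated from these libraries edgeR called 0 of 200 changed genes, so its counts of 0 say nothing about stability. DESeq2's Wald test called 399 genes, and simulated counts without any change gave it 84. The number of lists past the threshold was 1 with the replicate block, RLE scaling or no filter, 0 with an estimated correlation, and 0 to 3 without each replicate. It was 0 without control replicates 1 or 3 or 8 h replicate 2, 3 without control replicate 2 and 2 without 8 h replicate 3, where fewer samples were tested. With fry it was 1, the trafficking list in place of the cell cycle list. The cell cycle list's difference stayed at 1.64 and past the threshold with the replicate block and RLE scaling, and at 1.19 without a filter. It was 1.64 with an estimated correlation (adjusted p = 0.624) and with fry (adjusted p = 0.181), not past it, and 1.36 to 1.94 without each replicate. Over its alternatives the adjusted p ranged from 0.00271 to 0.624. The seed-site difference was negative in every alternative run and never passed, at -0.16 with the replicate block and -0.24 to -0.08 without each replicate. Among named genes, 142 values kept their sign without passing a threshold that edgeR could hardly reach here, 7 changed sign and 1 passed, Ifng in DESeq2 (adjusted p = 0.00437, against a range of up to 0.998). Among other lists 305 values kept direction and side, 21 changed sign and 4 passed. Fewer samples were tested where a replicate was left out, and camera's degrees of freedom changed with an estimated correlation. Other causes of the changed list calls were not tested. The filter left out genes with low counts, such as Cd4, and whether depth was the limit for them was not tested. The alternative pseudocount was not run, since the table holds counts.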

Other observations

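Tests of the edgeR counts and of the cell cycle list over the splits, of counting noise and of shared movement within lists were chosen after the result was seen. Interferon-response genes had higher values at 8 h in 12 of 19 tested members and lower values in 7 (camera adjusted p = 0.546). Ifit2, an antiviral effector, had 6, 12 and 250 counts in controls and 1225, 671 and 208 at 8 h, and Ifih1, a sensor of double-stranded RNA, had 10, 35 and 22 counts against 396, 741 and 156. Isg20, an exonuclease induced by interferon, had 679, 202 and 118 counts against 30, 108 and 87. Itgax, a myeloid integrin, had 535, 37 and 178 counts in controls and 38, 17 and 8 at 8 h, and Ms4a1, the B cell marker CD20, had 21, 15 and 30 against 324, 574 and 207. None of these 5 genes passed edgeR's test, DESeq2 called Ifih1, Itgax and Ms4a1, and all were chosen after their values were seen. Lower values at 8 h were more frequent in the autophagy and TGF-beta lists (8 of 10 members each) and among B cell markers (7 of 10), and dendritic cell markers split into 3 higher and 4 lower. Heat shock genes split into 6 higher and 3 lower, oxidative phosphorylation into 10 and 13, glycolysis into 8 and 6, cytosolic ribosomal proteins into 12 and 17, and apoptosis genes into 6 and 7. None of these lists passed the camera test, the lowest adjusted p among them being 0.312.

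The 6 libraries allow only 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes in edgeR, as did 10 of the 10 splits (highest other 0). DESeq2 called 399 genes in the real split, a number reached by 2 of the 10 splits (highest other 399). The number of lists past the camera threshold was 1, reached by 3 of the 10 splits (highest other 1), in the others by ribosome biogenesis or by Th17 genes. The cell cycle list's difference was 1.64 (highest other 1.26), with a camera p as low in 1 of the 10 splits, and edgeR's genes at an unadjusted p under 0.05 numbered 709 (highest other 690). The adjusted difference of genes with a miR-155 site was 0.173 in size, reached by 3 of the 10 splits (highest other 0.195). Over the other 7-mers of the same composition, a share of 0.0573 gave a difference as low as the miR-155 seed match. The lowest of them, ATATACG (-0.449), and the highest, CGATATA (0.770), both held the bases CG side by side, which AGCATTA lacks. Most of those lower than AGCATTA held CG. The ones without it were AAATTGC, TACAATG, CTAATAG, CTAGTAA, GATTCAA, GTACTAA and GTCTAAA (-0.279 to -0.218). The rank was not taken among 7-mers without CG alone, so it does not decide on a role of base composition.

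The 399 genes called by DESeq2 may reflect a test that calls many genes in these libraries however they are grouped. The median over the other 9 splits was 320 calls, with a lowest of 280, and simulated counts without any change gave 84. The treatment or the time of 8 h stays open as a source of part of the calls, which these values do not separate from the rest.

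Libraries of one group differed widely. For the 1065 tested genes with a mean of at least 1000 counts, noise from counting reads is argued against. Their median coefficient of variation within a group was 19 times the value that counting reads alone gives. Genes with fewer counts were not tested for it. As the reads carried no molecular identifiers, noise from the number of molecules sampled was not tested. GC content and transcript length acting differently in each library explained a share of 0.000799 of the residual variance on average. Cell state or cell make-up as the main source would have genes of a list move together, and the mean correlation of residuals within lists was 0.0287 ± 0.0175 (SE over 31 lists), which argues against it across the lists as a whole. Single lists ranged from -0.116 to 0.319, with the highest values for Th17 genes (0.319), erythroid markers (0.216) and JAK-STAT genes (0.177), so it may hold for some of them, and a source acting on single genes was not tested.

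Many ribosomal protein genes had few counts, 24 of the 50 in the table having at most 100 in each library, whereas 16 had a median of at least 1000. Rps6 had 0, 0, 1, 1, 1 and 0 counts and Rpl5 2, 1, 7, 4, 4 and 3, while Rplp0 had 19877 to 500556, and the cytoskeletal gene Actb, which T cells express abundantly, had 4, 1, 3, 4, 5 and 3. Reads spread over several RefSeq transcripts of one gene are argued against for the low genes as a set. The median number of transcripts was 1 in low and high genes alike, a difference of 0. For single genes such spreading stays open. Among low genes Rpl22 had 5 transcripts and Rps21 and Rps24 had 6 each, while the high gene Rps19 had 9. Reads shared with near-identical copies and left uncounted could account for part. The median share of 50-base windows found in no other gene was 0.368 in low and 0.505 in high genes, the value of the low genes lying between the bounds set for it in advance, and Rpl22 was low with a share of 0.948.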
